A study of Mus musculus with 32 samples.

How the data were processed

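Total RNA from immortalized mouse embryonic fibroblasts was extracted with a column kit, labelled with biotin and hybridised to an Illumina mouse bead array, per the labels' protocols. The labels place the 32 arrays in 10 groups, WT (floxed Spry1, Spry2 and Spry4) and KO (the 3 genes deleted) at 0, 15, 60, 120 and 240 min after FGF, with replicates A to D at 0 min and A to C at the other times. The deposited intensity values are linear, not normalized between arrays and already background-subtracted as their negative values show, and the submitters' processing notes name GenomeStudio 1.9.0. A deposited fraction per probe and array runs from near 0 for dim to 1 for bright probes and was read as 1 minus the detection p-value. Per the file headers, the bead counts and the bead standard deviation of each probe were deposited too, and were used only to set differences between arrays against bead noise. A further 128 columns of per-sample values were not used. The authors' series matrix holds a second deposited intensity per probe, whose column medians lie between 10.1 and 10.2, which keeps negative values and correlates at 0.999 or more on the log scale with the same array. It appears quantile-normalized and linear from its values, but its exact processing is not given in the sources used here, and it served as an alternative.

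Probe names came from the platform annotation: 23978 of 25697 probes have 1 gene symbol, 0 have several and 1719 have none. Of the symbols, 23962 were matched to the mouse RefSeq table (assembly GRCm38.p6) by gene ID and took its current name. The array's build is not named, so no coordinates are given and the table served only for names and for which genes are neighbours.

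Intensities were corrected with limma's neqc in R 4.3.3 (limma 3.58.1): normexp with the mean and SD of negative controls inferred from the detection p-values, an offset of 16, log2 and quantile normalization. A probe was kept if its detection p lay under 0.05 on at least 3 arrays, which left 14716 probes. The probe with the highest mean stood for a gene, giving 10903 tested genes, 10041 of them named and 862 unnamed probes. Of 2666 genes with several kept probes, 1683 had a probe called between KO and WT at 0 min and 22 of these had probes called in opposite directions. 1 model with the 10 group means was fitted over all 32 arrays with lmFit and eBayes (22 residual and 5.27 prior degrees of freedom), and a gene was called where its Benjamini-Hochberg adjusted p over the genes tested was under 0.05. Contrasts were KO against WT at each time and averaged over the 5 times, each time against 0 min within a genotype, and the difference of these responses between genotypes (an interaction, with an F-test over the 4 times). Standard errors are those of the moderated fit, and every adjusted p for a gene is limma's.

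Where a gene's probes were not detected on any array of 1 group, the text says not well above background and gives the brighter group's mean over the mean of, per array, the higher of the probe's own value and the lowest value among detected probes, as at least N-fold. A fitted difference of responses that involves such a group is no bound. No fold is given where both groups are below background.

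Before the data were examined, 33 gene lists (pathways, gene families and markers of other cell types), the tests, the alternatives and the rule for named genes were fixed. The 29 lists with 5 or more tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Every list was counted over all genes and adjusted over the list alone. Named genes were, for KO against WT at 0 min and the responses at 60, 120 and 240 min, drawn from the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap, and 5 and 5 at 15 min. Added were the 10 and 10 largest for a difference of responses and up to 4 called members of a list, leaving out unnamed transcripts, with Spry1 to Spry4 always given. Of these, the text names a part, and it says where a gene was chosen after its values were seen.

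Simulated data held 10903 genes, with 67, 67 and 66 changed by a log2 of 0.5, 1 and 2. Calls recovered 82.1%, 98.5% and 100% of these for KO against WT at 0 min, 64.2%, 100% and 100% for the WT response at 60 min, 58.2%, 100% and 100% for the KO response at 240 min, and 25.4%, 91% and 100% for the difference at 240 min. A list of 25 genes shifted by 0.3 was called in all 4 comparisons, and 0 of 19 unshifted lists in each. Lists of correlated genes may fare otherwise.

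Replicates of a group were compared with each other before averaging. Replicates A and D at 0 min were the closest pair in both genotypes, their mean squared difference being 1.67 (WT) and 1.73 (KO) times that of bead noise. Bead noise leaves out labelling and hybridisation, so this cannot show whether A and D are separate samples. Each array was counted, as the labels list it, and A and D were averaged as an alternative. Alternatives were quantile normalization of log2 values without normexp (shifted by 53 to lie above 0), median scaling over all probes, the authors' values (shifted by 42), no filter (18312 genes), a stricter filter (detection p under 0.01 on every array of a group, 8247 genes), the mean of a gene's probes, the replicate letter as a block, array weights, a fit of the compared groups alone, and each array left out. Median scaling over the kept probes and the averaging of A and D at 0 min were chosen after seeing the data. The files used here give no slide, so a slide block was not run.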

Results

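Gene expression was measured on 32 Illumina bead arrays, each carrying 25697 probes, in immortalized mouse embryonic fibroblasts (MEFs), connective tissue cells grown from mouse embryos. The cells either carried floxed but intact Spry1, Spry2 and Spry4 (WT) or had lost these genes by deletion (KO). Sprouty proteins are inhibitors of signalling from receptor tyrosine kinases to ERK that are themselves induced by the pathway. Cells were starved of serum in medium with 0.2% BSA and profiled at 0, 15, 60, 120 and 240 min after FGF, with 4 arrays per genotype at 0 min and 3 per genotype at each later time. Which FGF was given, and at what dose, is not given in the sources used here. The title of the series names Sprouty-mediated regulation of Wnt pathway genes as the question, and the design text names loss of feedback. Between 11319 and 12470 probes per array (44.0% to 48.5%) were detected above the negative controls, from a median of 35 to 41 beads per probe. WT arrays detected 11592 ± 179 probes and KO arrays 12070 ± 260 (mean ± SD, n = 16 arrays per genotype). The lowest intensity was -32.1 ± 2.83 on WT and -19.8 ± 1.64 on KO arrays (SD, n = 16 each). Across probes, which are not independent replicates, the median correlation between arrays was 0.994 within a group, 0.989 between times of a genotype and 0.963 between genotypes. The first principal component held 59.7% of the variance and separated the genotypes, and the second held 8.41%. The design text calls the replicates biological, but nothing says that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

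The Sprouty genes were examined in every array before any other gene. Neither Spry1, with 2 probes, nor Spry2, with 1, was well above background on more than 1 array of any group in either genotype, so their deletion could not be read from these arrays. Spry4 was detected on 4 of 4 WT and 1 of 4 KO arrays at 0 min and was lower in KO by 1.63-fold (log2 -0.71±0.13 SE, n = 4 per genotype, limma adjusted p = 6.88e-05). On KO arrays it was not well above background at 60 and 240 min, where it was at least 2-fold lower than in WT (adjusted p = 2.48e-07 and 2.34e-07). At 120 min it was detected on all arrays of both genotypes and was 1.92-fold lower in KO (-0.94±0.15, adjusted p = 1.06e-05), and at 15 min on no array of either. Where the Spry4 probe lies relative to the deleted part is not given in the sources used here, and a probe outside it checks nothing. Spry3, which the labels do not list as deleted, was detected on every WT array and on no KO array. It was at least 2.91-fold lower in KO at 0 min, and at least 4.68-, 3.28-, 3.58- and 4.85-fold lower at 15, 60, 120 and 240 min (adjusted p = 2.53e-16 at 0 min). In WT, Spry3 rose at 15 min (log2 0.67±0.10, adjusted p = 0.000215), at 120 min (0.36±0.10, 0.037) and at 240 min (0.75±0.10, 3.48e-06), with 0.16±0.10 at 60 min (adjusted p = 0.453). WT Spry4 was not well above background at 15 min, at least 1.43-fold lower than at 0 min (adjusted p = 0.00827), and rose at 120 min (0.68±0.14, adjusted p = 0.00378) and 240 min (0.42±0.14, adjusted p = 0.0441). In KO it rose at 120 min (0.44±0.14, adjusted p = 0.0353, from 1 of 4 arrays detected to 3 of 3). Some of these calls rested on single arrays. Leaving out 1 array ended that of Spry3 in WT at 120 min for 4 of 7 arrays (adjusted p = 0.174 without WT 120 min replicate C). The same held for Spry4 in WT at 15 min for 1 of 7 (0.0572 without WT 15 min replicate C), in WT at 240 min for 5 of 7 (0.233 without WT 240 min replicate A) and in KO at 120 min for 5 of 7 (0.159 without KO 120 min replicate C).

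**Figure D1:**
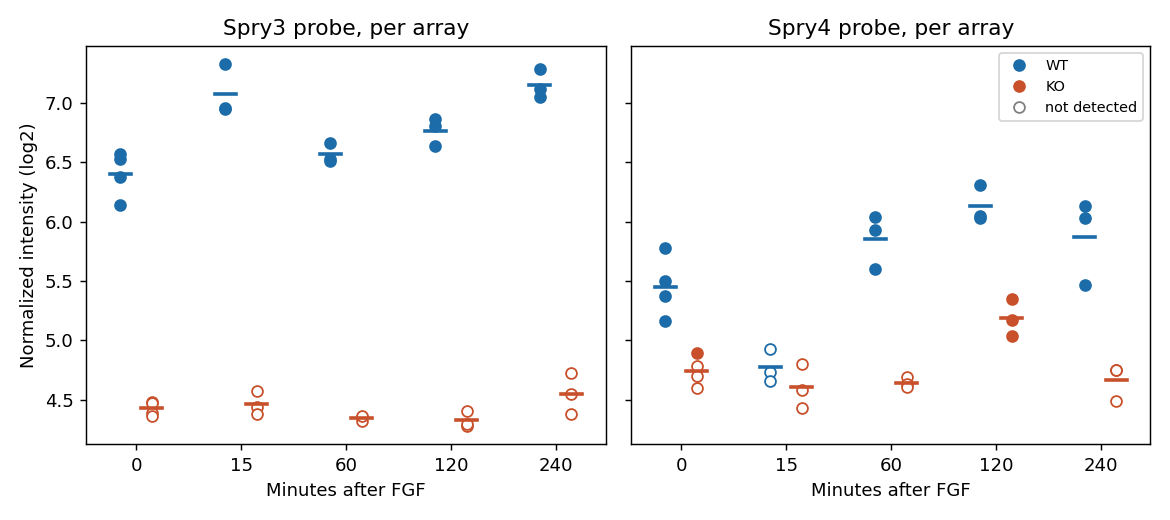
Normalized log2 intensity of the Spry3 and Spry4 probes (y axes) on each of the 32 arrays by time after FGF in minutes (x axis), for WT and KO; filled points are detected above background and open points are not. Spry3 is detected on every WT array and on no KO array, and Spry4 on 4 of 4 WT and 1 of 4 KO arrays at 0 min.

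Before FGF, KO cells differed from WT in 4995 of 10903 genes (45.8%), 2416 of them higher and 2579 lower in KO, with 348 and 195 past 2-fold. Igfbp7, a secreted binding protein of insulin-like growth factors, was 99.8-fold higher in KO (log2 6.64±0.083 SE, n = 4 arrays per genotype, limma adjusted p = 8.1e-30). The neutrophil-attracting chemokine Cxcl1 was 25.3-fold higher (4.66±0.099) and Sncg, which encodes gamma-synuclein, 20.4-fold higher (4.35±0.082). The innate immune pentraxin Ptx3 was 36.2-fold and the acute-phase gene Saa3 24.8-fold higher, each from WT arrays of which 2 of 4 detected it. Ptn, the growth factor pleiotrophin, was at least 23.6-fold higher, Pdzrn3 at least 26.1-fold, the imprinted gene Dlk1 at least 20.7-fold, the acute-phase gene Lcn2 at least 17.1-fold and Svop at least 20.9-fold, all not well above background in WT. In the other direction, the secreted factor Angptl7 was at least 124-fold lower, the limb transcription factor Osr2 at least 51.2-fold, the ligand Fgf5 at least 15.2-fold and Igfbp5 at least 16.3-fold, all not well above background in KO. The Wnt ligand Wnt7b was 28.3-fold lower (-4.82±0.078), the growth factor Igf2 17.2-fold (-4.11±0.091), Rgcc 13.8-fold, the homeobox gene Rhox5 13.4-fold, the chemokine Ccl17 12.4-fold and the FGF carrier Fgfbp1 12.2-fold lower. The highest adjusted p among these 20 genes was 5.23e-18, for Fgfbp1, and for each of them no array of 1 genotype overlapped those of the other. Of the genes called, 48.4% were higher in KO, 66.9% with median scaling over all probes and 38% with median scaling over the kept probes.

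Several fixed lists stood apart from the other genes at 0 min. Of 22 cytokine and NF-kappaB genes, 16 were higher in KO, 1 was lower and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 3.79e-07). Among them were the chemokine Ccl7 (3.14±0.12), the macrophage growth factor Csf1 (2.60±0.12) and Nfkbiz (1.61±0.082). Of 24 ribosome biogenesis genes, 19 were lower and 5 not called (20 lower adjusted over the list alone), such as Noc4l (-0.99±0.072) and Pes1 (-0.93±0.069; camera adjusted p = 3.79e-07). Of 25 ER stress and amino acid response genes, 2 were higher, 17 were lower and 6 did not pass (3 were higher and 18 were lower adjusted over the list alone, camera adjusted p = 4.71e-05). Shmt2 (-1.55±0.090), Ddit3 (-1.34±0.086) and asparagine synthetase Asns (-1.30±0.061) were lower and the lipoprotein receptor Vldlr (1.48±0.12) higher. Of 19 matrix proteases and inhibitors 10 were higher, 3 were lower and 6 did not pass (10 were higher and 4 were lower adjusted over the list alone, camera adjusted p = 0.00568, adjusted p = 0.0774 with an estimated correlation). The stromelysin Mmp3 was 17.1-fold higher (3 of 4 WT arrays detected it) and the collagen-degrading Ctsk at least 11.1-fold. Of 24 G1/S and DNA replication genes 2 were higher, 14 were lower and 8 did not pass (2 were higher and 15 were lower adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.447 with an estimated correlation). Ung (-1.35±0.13), Mcm7 (-0.76±0.11) and Mcm5 (-0.76±0.10) were lower and Rrm2 (0.86±0.12) higher. The other lists did not pass camera, with members moving both ways. Among extracellular matrix genes 13 were higher and 9 lower of 28 (decorin Dcn -3.36±0.073, and Thbs2 3.31±0.12 with 3 of 4 WT arrays detecting it). The 17 SRF/MRTF and actin genes split 5 and 4, Acta2 at 2.44±0.084, with a median of -0.08 but a mean of 0.18. ERK output and feedback genes split 6 higher and 9 lower of 19, with Hbegf at -1.56±0.086 and Fosl1 at 1.03±0.13. Immediate early genes split 6 and 6 of 26, FGF receptors, ligands and adaptors 4 and 3 of 17, and other growth factor receptors 6 and 3 of 16. G2/M genes split 3 and 2 of 18, cholesterol biosynthesis 8 and 4 of 17, and interferon-stimulated genes 7 and 5 of 17. The split was 8 and 3 of 17 for p53 targets (Fas 2.63±0.13), and for TGF-beta and BMP response genes 8 and 3 of 20. Glycolysis and hypoxia genes split 7 and 3 of 19, and heat-shock and handling stress genes 2 and 3 of 12. Adjusted over the list alone, the counts of these lists differed by at most 1 gene from those over all genes.

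Members of the lists that describe the origin of the cells, and of the marker lists of other cell types, were also called, but none of these lists that were tested passed camera. Of 27 Hox and limb position genes, 3 were higher, 9 were lower and 15 did not pass (the same adjusted over the list alone, camera adjusted p = 0.105). Hoxd10 was 4.2-fold lower in KO (3 of 4 KO arrays detected it), Hoxb7 at least 2.13-fold lower and Hoxb5 at least 1.63-fold higher. Of 10 imprinted growth genes 4 were higher and 4 lower, with Ndn at least 13.4-fold and Mest 8.37-fold higher, a median of -0.03 and a mean of 0.56. Neither of the 2 sex-linked genes tested was called by limma at 0 min, and 0 passed at an unadjusted p under 0.05 (Xist -0.17±0.21, adjusted p = 0.543). Averaged over the 5 times both were called, with Xist higher (0.62±0.10, adjusted p = 6.77e-06) and Uty lower in KO (-0.16±0.062, adjusted p = 0.0288), values chosen after they were seen. Uty was called higher in KO at 15 min (0.44±0.14) and lower at 60 and 120 min (-0.49±0.14 and -0.53±0.14), where 2 of 3 and 1 of 3 KO arrays detected it. Fibroblast markers split 5 higher and 4 lower of 12, neural and glial markers 2 and 3 of 7 (Gap43 -3.49±0.096, 3 of 4 KO arrays detecting it) and epithelial markers 1 and 2 of 6 (keratin gene Krt8 -1.73±0.12). Macrophage and leukocyte markers were higher for 3 of 5 (lysozyme gene Lyz1 2.19±0.13, from 2 of 4 WT arrays) and endothelial markers for 2 of 4. Adipocyte markers were higher for 2 and lower for 1 of 3, and skeletal muscle and chondrocyte and osteoblast markers were each lower for 1 of 5. The last list had a median of 0.18, a mean of -0.07 and a downward camera direction. The endothelial, adipocyte, sex-linked and Sprouty lists had fewer than 5 tested members and were only counted.

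At the later times the genotypes differed in 4353, 4579, 4775 and 4782 genes at 15, 60, 120 and 240 min (n = 3 per genotype). Averaged over the 5 times they differed in 7351 genes, 3465 higher and 3886 lower in KO. The averaged difference kept the lists of the 0 min comparison. Of cytokine and NF-kappaB genes 20 were higher and 2 did not pass (the same adjusted over the list alone). Of ribosome biogenesis genes 23 were lower and 1 did not pass (the same adjusted over the list alone). Of ER stress and amino acid response genes 2 were higher, 20 were lower and 3 did not pass (the same adjusted over the list alone). Of G1/S and DNA replication genes 2 were higher and 22 were lower (the same adjusted over the list alone), with camera adjusted p = 3.67e-06, adjusted p = 0.124 with an estimated correlation. Of matrix proteases and inhibitors 12 were higher, 2 were lower and 5 did not pass (the same adjusted over the list alone), with camera adjusted p = 0.000279. The share of called genes that were higher in KO was 49.9% at 60 min, 48.4% at 120 min and 49.9% at 240 min. Median scaling over the kept probes gave 39.5% at 60 and 38.7% at 240 min. Median scaling over all probes gave 28.8% at 120 min, where it moved the median of all genes to -0.12.

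FGF responses were read against each genotype's 0 min arrays. With no untreated later arrays, they may also reflect handling or time. At 15 min Egr1 rose 2.88-fold in WT (log2 1.53±0.15 SE, n = 3 and 4 arrays, limma adjusted p = 4.32e-07). In KO it rose 3.46-fold (1.79±0.15, 4.78e-08). Fos rose 2.61-fold in WT (1 of 4 arrays at 0 min detected it) and 2.27-fold in KO (3 of 4). In WT, Txnip (1.39±0.12), Bbc3 (1.07±0.11), which encodes the cell death inducer PUMA, and Trib2 (0.93±0.097) also rose. The semaphorin Sema7a fell to 1 of 3 arrays detected (-1.40±0.14), and Nppb (-1.16±0.16), Dok3 (-0.84±0.12) and Xist (-0.98±0.22) fell. In KO, the cytokine Csf2 rose at least 1.84-fold from not well above background. The mRNA-decay factor Zfp36 (0.96±0.14) and Rgs16 (0.84±0.12) rose, and Osgin1 (-0.78±0.14) and Dok3 (-0.73±0.12) fell. In all, 250 genes were called in WT (124 up, 126 down) and 89 in KO (43 up, 46 down). In WT p53 target genes passed camera, and of 17 genes 4 rose, 1 fell and 12 did not pass (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.225 with an estimated correlation). In KO, of the 19 ERK output and feedback genes 5 rose and 14 did not pass (6 rose adjusted over the list alone, camera adjusted p = 4.65e-05). There too, of the 22 cytokine and NF-kappaB genes 3 rose and 19 did not pass (6 rose adjusted over the list alone, camera adjusted p = 7.88e-05). Of immediate early genes in KO 7 rose, 1 fell and 18 did not pass (10 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.000814, adjusted p = 0.209 with an estimated correlation). G2/M genes passed camera in KO as well, where of 18 genes 2 fell and 16 did not pass (7 fell adjusted over the list alone, adjusted p = 0.209 with an estimated correlation). Ribosome biogenesis genes did so too, where of 24 genes 1 rose and 23 did not pass (the same adjusted over the list alone, adjusted p = 0.228 with an estimated correlation). So did G1/S genes, with a median of -0.19 and 0 of 24 called by limma and 7 at an unadjusted p under 0.05 (adjusted p = 0.228 with an estimated correlation). Extracellular matrix genes had a median of 0.11 and 0 of 28 called by limma and 5 at an unadjusted p under 0.05 (adjusted p = 0.471 with an estimated correlation). SRF/MRTF genes had a median of 0.09 and 0 of 17 called by limma and 2 at an unadjusted p under 0.05 (adjusted p = 0.298 with an estimated correlation). The WT count was 101 without WT 15 min replicate B and 134 without replicate C. The KO count was 20 and 26 without KO 15 min replicates A and B and 42, 59 and 44 without KO 0 min replicates A, B and D. Without 1 array the call of Xist ended (adjusted p = 0.177 without WT 15 min replicate B, and lost without replicate C). So did those of KO Fos (0.195 without KO 15 min replicate A, and lost without KO 0 min replicate D) and KO Dok3 (0.0512 without KO 15 min replicate A). Of the genes called, 49.6% rose in WT and 48.3% in KO, against 75.2% and 22.2% with median scaling over all probes.

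At 60 min immediate early genes, the transcription factors and feedback genes that need no new protein for their induction, led both responses. In WT, Egr2 was 7.97-fold higher than at 0 min (log2 2.99±0.14 SE, n = 3 and 4, adjusted p = 3.78e-15). Also up were Csrnp1 (2.80±0.11), Ier3 (2.49±0.085), Egr1 (2.46±0.15), Ccn2 (2.39±0.11), Sgk1 (2.26±0.067), Cxcl1 (2.18±0.11), Chac1 (2.16±0.11) and Atf3 (2.15±0.13). Fosb rose at least 4.67-fold from not well above background. In KO, Egr2 was 15-fold higher (3.91±0.14, adjusted p = 2e-17). With it rose Egr1 (3.42±0.15), Zfp36 (2.95±0.14), Csrnp1 (2.55±0.11), Junb (2.38±0.10), Rgs16 (2.34±0.12), Lif (2.05±0.16) and Ier3 (1.92±0.085). Fosb rose at least 5.05-fold, and Fos 9.95-fold from 3 of 4 arrays detecting it at 0 min. The genes that fell were smaller in change. In WT they included Otx1 (-1.35±0.15), Zfp41 (-1.28±0.11), Foxc1 (-1.22±0.13) and Hoxa2 (-0.89±0.13), of which all but the zinc finger gene Zfp41 are developmental homeobox or forkhead genes. In KO they included Zkscan14 (-1.01±0.11), Zfp87 (-0.75±0.076) and Hoxa2 (-0.68±0.13). Of 26 immediate early genes, 17 rose and 9 did not pass (20 rose adjusted over the list alone) in WT. In KO, 19 rose, 2 fell and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 1.88e-47 in WT and 3.72e-47 in KO). Of 19 ERK output and feedback genes, 11 rose, 1 fell and 7 did not pass (11 rose and 2 fell adjusted over the list alone) in WT and 11 rose and 8 did not pass (the same adjusted over the list alone) in KO. Phlda1 (2.02±0.10 and 1.64±0.10) and, in KO, Hbegf (1.58±0.093) were among them, and camera gave an adjusted p of 1.95e-21 and 7.33e-22. Cytokine and NF-kappaB genes passed too, where of 22 genes 9 rose and 13 did not pass (11 rose and 2 fell adjusted over the list alone) in WT and 8 rose and 14 did not pass (11 rose adjusted over the list alone) in KO (camera adjusted p = 3.52e-10 and 1.47e-06). They included Tnfaip3 in WT (1.70±0.12). The cytokine Lif, a member of the ERK list, rose in WT (1.49±0.16, 2 of 4 arrays at 0 min detecting it), and of the cytokine list the prostaglandin synthase Ptgs2 rose in both (1.51±0.17 in WT, 1.10±0.17 in KO). Among 17 p53 target genes 8 rose and 9 did not pass (9 rose adjusted over the list alone) in WT and 4 rose and 13 did not pass (7 rose adjusted over the list alone) in KO (camera adjusted p = 8.38e-10 and 0.000117). Bbc3 lay at 1.46±0.11 and 0.84±0.11, and Mdm2 at 1.39±0.088 and 0.73±0.088. Of 20 TGF-beta and BMP response genes 5 rose, 1 fell and 14 did not pass (the same adjusted over the list alone) in WT and 5 rose and 15 did not pass (7 rose adjusted over the list alone) in KO (camera adjusted p = 0.0111 and 4.9e-05). These 5 lists also passed in both genotypes with an estimated correlation.

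Further lists passed camera at 60 min in 1 genotype or lost their call with an estimated correlation. Of 19 matrix proteases and inhibitors, 4 rose and 15 did not pass (the same adjusted over the list alone) in WT (camera adjusted p = 0.00665, adjusted p = 0.0618 with an estimated correlation). In KO 5 rose and 14 did not pass (8 rose adjusted over the list alone, camera adjusted p = 1.61e-05), with the protease Adamts1 (1.03±0.14) up. Of 17 FGF receptors, ligands and adaptors, 3 rose, 1 fell and 13 did not pass (3 rose and 2 fell adjusted over the list alone) in WT (camera adjusted p = 0.00665, adjusted p = 0.0618 with an estimated correlation), where the ligand Fgf7 lay at 0.68±0.10. In KO 3 rose and 14 did not pass (5 rose adjusted over the list alone, camera adjusted p = 0.0035, adjusted p = 0.0558 with an estimated correlation). G1/S genes passed in WT, where of 24 genes 1 rose and 23 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.459 with an estimated correlation). Ribosome biogenesis genes passed downward in KO, where of 24 genes 4 fell and 20 did not pass (the same adjusted over the list alone, camera adjusted p = 5.36e-05). Of 17 cholesterol biosynthesis genes in KO, 3 fell and 14 did not pass (1 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.000667, adjusted p = 0.0993 with an estimated correlation). Of 16 other growth factor receptors in KO, 5 rose and 11 did not pass (6 rose adjusted over the list alone, camera adjusted p = 0.000199, adjusted p = 0.168 with an estimated correlation). Extracellular matrix genes passed in KO, where of 28 genes 2 rose and 26 did not pass (3 rose adjusted over the list alone, camera adjusted p = 0.00632, adjusted p = 0.47 with an estimated correlation). Thbs1 rose among them (1.08±0.21), and their median of 0.10 turned to -0.02 with median scaling over all probes. In total 572 genes were called in WT (343 up, 229 down) and 617 in KO (348 up, 269 down). The share up was 60% in WT and 56.4% in KO, against 83.5% and 21.7% with median scaling over all probes. The WT count was 375 without WT 60 min replicate A. The KO count was 258 without KO 60 min replicate C, 354 without KO 0 min replicate A and 337 without KO 0 min replicate D.

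At 120 min the cytokine Lif was 8.28-fold higher than at 0 min in KO (log2 3.05±0.16 SE, n = 3 and 4, adjusted p = 3.17e-14). Csf2 rose at least 5.78-fold, and Il6 4.18-fold with 1 of 4 arrays at 0 min detecting it. Further rises in KO were Rgs16 (2.14±0.12), Ier3 (2.13±0.085), Sema7a (2.13±0.14), Hbegf (2.06±0.093) and S100a8 (1.91±0.11). Rises in WT included Sema7a (1.92±0.14), Plau (1.59±0.12), Ier3 (1.53±0.085), Rgs16 (1.31±0.12) and Jun (1.29±0.11), Plau being the urokinase-type plasminogen activator. Runx1t1 and Sertad4 fell in WT (-1.14±0.13 and -1.09±0.11) and in KO (-1.60±0.13 and -1.33±0.11). In WT, Pik3ip1 fell at least 1.98-fold, and Ccng2 (-0.92±0.12) and Hoxc6 (-0.88±0.089) fell. In KO the endothelin gene Edn1 fell to 1 of 3 arrays detected (-1.90±0.18), and Rnd3 (-1.48±0.14) and Bmp4 (-1.14±0.16) fell. Of 19 ERK output and feedback genes, 10 rose and 9 did not pass (12 rose adjusted over the list alone) in WT (camera adjusted p = 4.79e-25). In KO 11 rose and 8 did not pass (11 rose and 2 fell adjusted over the list alone, camera adjusted p = 2.53e-17). Of 26 immediate early genes 7 rose, 3 fell and 16 did not pass (9 rose and 3 fell adjusted over the list alone) in WT (camera adjusted p = 5.8e-05, adjusted p = 0.0629 with an estimated correlation). In KO 16 rose, 3 fell and 7 did not pass (17 rose and 3 fell adjusted over the list alone, camera adjusted p = 9e-14). Of 22 cytokine and NF-kappaB genes 5 rose, 1 fell and 16 did not pass (7 rose and 1 fell adjusted over the list alone) in WT, and 8 rose, 2 fell and 12 did not pass (11 rose and 3 fell adjusted over the list alone) in KO (camera adjusted p = 9.73e-05 and 7.79e-05). G1/S genes passed downward in KO, where of 24 genes 9 fell and 15 did not pass (11 fell adjusted over the list alone, camera adjusted p = 0.000204, adjusted p = 0.22 with an estimated correlation). Of 18 G2/M genes, which did so as well, 7 fell and 11 did not pass (9 fell adjusted over the list alone, camera adjusted p = 0.000204, adjusted p = 0.22 with an estimated correlation). Of 17 p53 target genes in WT, 6 fell and 11 did not pass (2 rose and 10 fell adjusted over the list alone, camera adjusted p = 3.25e-05). Glycolysis and hypoxia genes passed in WT, where of 19 genes 4 rose and 15 did not pass (4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0223). In KO 5 rose, 1 fell and 13 did not pass (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00573), and their median of 0.11 turned to -0.17 with median scaling over all probes. Matrix proteases and inhibitors passed in KO, where of 19 genes 7 rose, 2 fell and 10 did not pass (8 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.000121). Of 20 TGF-beta and BMP response genes in KO, 8 rose, 2 fell and 10 did not pass (9 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.0155). Hox and limb position genes passed downward in WT, where of 27 genes 1 rose, 5 fell and 21 did not pass (1 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.0484, adjusted p = 0.0716 with an estimated correlation). In KO 3 rose, 8 fell and 16 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0458, adjusted p = 0.0775 with an estimated correlation). Ribosome biogenesis genes passed in WT with a median of 0.08 and 0 of 24 called by limma and 2 at an unadjusted p under 0.05 (adjusted p = 0.32 with an estimated correlation).

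In all 438 genes were called in WT at 120 min (222 up, 216 down), and 291 without WT 120 min replicate C. In KO 1654 were called (669 up, 985 down). The share up was 50.7% in WT and 40.4% in KO, against 75.2% and 5.61% with median scaling over all probes, which moved the median of all genes in KO to -0.21. Over the kept probes it was 61.9% in KO.

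At 240 min in WT, the matrix-degrading enzyme Mmp3 was 19.3-fold higher than at 0 min (log2 4.27±0.15 SE, n = 3 and 4, adjusted p = 6.98e-18, with 3 of 4 arrays at 0 min detecting it). The related Mmp10 was 9.44-fold higher (2 of 4 arrays), with Mcpt8 (2.77±0.16), Plau (2.54±0.12), Tnc (2.38±0.14), Sema7a (2.15±0.14) and Mgp (2.08±0.12). In KO, the calcium-binding S100a8 was 14.6-fold higher (3.87±0.11, adjusted p = 2.69e-20) and Serpinb2 at least 6.85-fold. There, Mmp10 (3.60±0.16), Sema7a (3.10±0.14), Mmp3 (2.77±0.15), Mmp13 (2.58±0.13), Tnc (2.48±0.14), Upp1 (2.29±0.11) and Il11 (2.23±0.12) also rose. Falls in WT included Adamts4 (-2.10±0.14), Diras2 (-1.92±0.11), Sertad4 (-1.70±0.11), Osr2 (-1.65±0.11) and Foxc1 (-1.60±0.13). Those in KO included Bmp4 (-2.65±0.16), Rnd3 (-1.86±0.14), Sertad4 (-1.76±0.11) and Edn1 (-1.75±0.18, 2 of 3 arrays detecting it). Of 24 G1/S and DNA replication genes, 9 rose and 15 did not pass (the same adjusted over the list alone) in WT (camera adjusted p = 4.83e-06, adjusted p = 0.181 with an estimated correlation). Those that rose included Ung, which removes uracil from DNA (1.36±0.14), the replication licensing genes Cdc6 (1.18±0.14) and Cdt1 (1.07±0.10), and Ccne2 (1.09±0.20). In KO 8 fell and 16 did not pass (10 fell adjusted over the list alone) of the same list, with Tk1 (-0.66±0.12), Ung (-0.65±0.14) and Mcm5 (-0.48±0.11) (camera adjusted p = 0.0012, adjusted p = 0.336 with an estimated correlation). Of ERK output and feedback genes 12 rose and 7 did not pass (12 rose and 1 fell adjusted over the list alone) in WT, with Dusp6 (1.11±0.086) and Ier3 (1.17±0.085) up (camera adjusted p = 2.5e-09). In KO 13 rose and 6 did not pass (the same adjusted over the list alone), with Lif (1.94±0.16), Plaur (1.49±0.078), Hbegf (1.46±0.093) and Ier3 (1.82±0.085) (camera adjusted p = 4.16e-16). Of 24 ribosome biogenesis genes 13 rose and 11 did not pass (17 rose adjusted over the list alone) in WT, such as Rrp9 (0.53±0.093) and Nop56 (0.42±0.10; camera adjusted p = 8.33e-07). In KO 15 rose and 9 did not pass (17 rose adjusted over the list alone), with Nop2 (0.67±0.11) and Heatr1 (0.60±0.086; camera adjusted p = 2.44e-07).

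In KO at 240 min, of 19 matrix proteases and inhibitors 9 rose, 4 fell and 6 did not pass (10 rose and 4 fell adjusted over the list alone, camera adjusted p = 3.78e-05). Of 17 p53 target genes 9 fell and 8 did not pass (the same adjusted over the list alone), with the death receptor Fas at -1.14±0.14 and Plk2 at -1.12±0.10 (camera adjusted p = 0.000123). Glycolysis and hypoxia genes passed, and of 19 genes 5 rose, 1 fell and 13 did not pass (5 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.0226). The glucose transporter Slc2a1 (1.29±0.081), hexokinase Hk2 (1.20±0.095) and the angiogenic factor Vegfa (1.12±0.090) rose. Of 22 cytokine and NF-kappaB genes, 6 rose, 3 fell and 13 did not pass (9 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.0306). Of 17 FGF receptors, ligands and adaptors, 6 rose, 2 fell and 9 did not pass (8 rose and 2 fell adjusted over the list alone), with the FGF receptor-binding protein Flrt3 at 1.88±0.11 (camera adjusted p = 0.0312, adjusted p = 0.184 with an estimated correlation). In WT 3 lists passed downward. Of 17 SRF/MRTF and actin genes 4 fell and 13 did not pass (6 fell adjusted over the list alone, camera adjusted p = 0.00741, adjusted p = 0.181 with an estimated correlation). Of 17 cholesterol biosynthesis genes 5 fell and 12 did not pass (1 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.252 with an estimated correlation). Of 27 Hox and limb position genes 1 rose, 9 fell and 17 did not pass (the same adjusted over the list alone, camera adjusted p = 0.00851). WT Fgf5 fell by 1.20 on the log2 scale (adjusted p = 1.18e-12), while in KO it was not well above background at any time. In total 1743 genes were called in WT (835 up, 908 down) and 2322 in KO (1109 up, 1213 down). Of the KO genes 47.8% were up, against 28.3% with median scaling over all probes.

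Set against each other at 60 min, both genotypes raised 143 genes and lowered 60, where independent lists of those lengths would share 10.9 and 5.65. At 15 min the shared genes were 15 up and 16 down (0.489 and 0.532 for independent lists), at 120 min 154 and 120 (13.6 and 19.5), and at 240 min 358 and 396 (84.9 and 101). Genes called in opposite directions numbered 1, 2, 5 and 80 at 15, 60, 120 and 240 min. Across the genes called in either genotype, which are not independent replicates, Pearson's r of the log2 responses was 0.642, 0.713, 0.652 and 0.557 at the 4 times, and 0.313, 0.450, 0.423 and 0.452 across all genes. The 2 responses have separate 0 min arrays, so no control was shared.

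**Figure D2:**
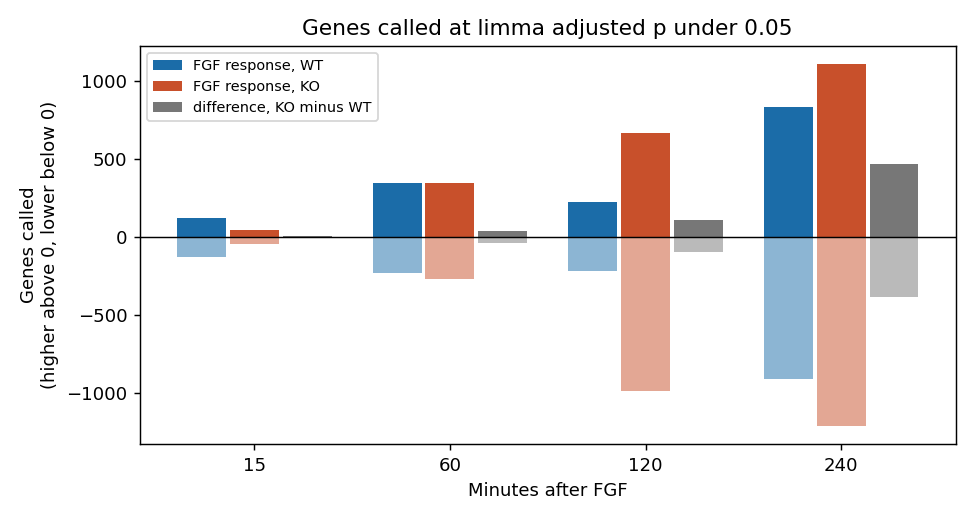
Number of genes called up (above 0) and down (below 0) by limma (y axis) at each time after FGF in minutes (x axis), for the response in WT, the response in KO and the difference between them. The largest bars are those of 240 min, 835 up and 908 down in WT and 1109 up and 1213 down in KO, with 471 and 386 for the difference.

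The response of KO cells was tested against that of WT cells as the difference between the 2 responses, for which positive values mean a higher response in KO. At 15 min the semaphorin gene Sema7a (1.35±0.20 SE on the log2 scale, n = 3 and 4 arrays per genotype, limma adjusted p = 0.00116) and the EGF-family ligand Hbegf (0.88±0.13, 0.00116) had the higher response in KO, Sema7a being detected on 1 of 3 WT arrays at that time. The feedback inhibitor of EGF receptors Errfi1 (0.71±0.097, adjusted p = 0.000727), Id1 (0.68±0.12, 0.0192) and Klf2 (0.60±0.12, 0.0351) did so as well. In all 6 genes differed, 5 of them with the higher response in KO, the remaining gene being an unnamed transcript. Of the 5, 4 had fallen in WT, 0 had risen in WT and 2 had risen in KO. By limma 758 passed at an unadjusted p under 0.05. ERK output and feedback genes passed camera, with 2 members higher in KO and 17 not called (4 higher in KO adjusted over the list alone) of 19 (camera adjusted p = 6.93e-06). So did cytokine and NF-kappaB genes with a median of 0.14 and 0 of 22 called by limma and 5 at an unadjusted p under 0.05, or 2 adjusted over the list alone (camera adjusted p = 0.000766). Immediate early genes passed with 1 higher and 25 not called (2 higher adjusted over the list alone, camera adjusted p = 0.00399, adjusted p = 0.215 with an estimated correlation). The 6 further lists that passed had 0 genes called by limma, and all lost the call with an estimated correlation. For G1/S genes 4 of 24 passed at an unadjusted p under 0.05 (median -0.18, adjusted p = 0.157 with an estimated correlation). For G2/M genes 2 of 18 did (median -0.12, adjusted p = 0.651), and for p53 targets 6 of 17 (-0.14, adjusted p = 0.281), both with an estimated correlation. For Hox and limb position genes 5 of 27 did (median -0.10, adjusted p = 0.109 with an estimated correlation). For SRF/MRTF genes the number was 1 of 17 (0.15, adjusted p = 0.109), and for ribosome biogenesis genes 3 of 24 (0.14, adjusted p = 0.109), both with an estimated correlation. The count was 3 without WT 0 min replicate A, WT 15 min replicate C, or KO 15 min replicate B or C. Leaving out 1 array ended the call of Id1 for 5 of 14 arrays (adjusted p = 0.0824 without KO 15 min replicate C) and of Klf2 for 10 of 14 (0.139 without KO 15 min replicate A). Median scaling over all probes ended those of Errfi1, Id1 and Klf2. It moved the median of all genes to -0.12 and the share with higher response in KO from 83.3% to 33.3%. Without normexp that share was 53.8%.

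At 60 min 77 genes differed, 39 with a higher and 38 with a lower response in KO. Zfp36, whose protein speeds decay of cytokine mRNAs, responded 2.75-fold more in KO (1.46±0.20 SE, n = 3 and 4, adjusted p = 0.000176), as did the transcription factors Klf2 (1.005±0.12, 8.12e-06) and Egr1 (0.96±0.22, 0.0285) and the X-inactivation RNA Xist (1.62±0.32, 0.00815). Cxcl1, already higher in KO at 0 min, responded 3.13-fold less in KO by a log2 difference of -1.65±0.15 (adjusted p = 2.06e-07). The responses of Chac1 (-1.51±0.15), Hes1 (-1.06±0.19), Tnfaip3 (-0.97±0.17) and Gadd45g (-0.92±0.11) were also lower, Hes1 being a Notch target and Tnfaip3 a brake on NF-kappaB. Of the genes with a lower response in KO, 32 had risen in WT. Among the lists, p53 target genes passed camera downward, with 2 lower and 15 not called (4 lower adjusted over the list alone) of 17 (camera adjusted p = 0.0143, adjusted p = 0.141 with an estimated correlation). The call of Egr1 ended without any of 9 of the 14 arrays (adjusted p = 0.117 without KO 60 min replicate C). Of the called genes 50.6% had the higher response in KO, against 9.86% with median scaling over all probes, which moved the median of all genes to -0.17.

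At 120 min 203 genes differed, 109 with a higher and 94 with a lower response in KO. Lif responded 4.4-fold more in KO (2.14±0.22 SE, n = 3 and 4, adjusted p = 5.62e-07, with 2 of 4 WT arrays at 0 min detecting it). Il11 (1.35±0.18), the cytokine signalling inhibitor Socs3 (1.41±0.13) and the transcription factor Csrnp1 (1.40±0.15) did so too. Il6 (2.10±0.22) was detected on 2 of 4 WT and 1 of 4 KO arrays at 0 min and on 2 of 3 WT arrays at 120 min. For Csf2 (2.80±0.23), not well above background on any WT array or in KO at 0 min, and S100a8 (1.83±0.15), not well above background on any WT array, the fitted difference is no bound. Edn1 (-1.26±0.25, detected on 1 of 3 arrays per genotype at 120 min), the sliding clamp gene Pcna (-1.20±0.29) and Rnd3 (-0.88±0.20) responded less. Of the genes higher in this test, 93 rose in KO, and of those lower, 69 fell in KO. Immediate early genes passed camera with 8 higher, 1 lower and 17 not called (11 higher and 1 lower adjusted over the list alone) of 26 (camera adjusted p = 4.53e-08). G1/S genes did so with 4 lower and 20 not called (7 lower adjusted over the list alone) of 24 (camera adjusted p = 9.36e-06, adjusted p = 0.24 with an estimated correlation). Matrix proteases and inhibitors passed with 3 higher and 16 not called (7 higher adjusted over the list alone) of 19 (camera adjusted p = 0.000139), their median of 0.20 turning to -0.06 with median scaling over all probes. ERK output and feedback genes passed with 5 higher and 14 not called (5 higher and 2 lower adjusted over the list alone) of 19 (camera adjusted p = 0.00657, adjusted p = 0.119 with an estimated correlation), their median of 0.09 turning to -0.18 under the same scaling. The cytokine and NF-kappaB list did not pass camera (adjusted p = 0.437), with 3 higher, 1 lower and 18 not called (4 higher and 2 lower adjusted over the list alone) of 22. G2/M genes passed downward with 0 of 18 called by limma and 7 at an unadjusted p under 0.05 (adjusted p = 0.564 with an estimated correlation). The count was 125 and 126 without WT 120 min replicates B and C and 135 without KO 120 min replicate A. The call of Pcna ended for 5 of 14 left-out arrays (adjusted p = 0.0786 without WT 120 min replicate B) and that of Rnd3 for KO 120 min replicate A (0.0667) and WT 120 min replicate C. The share with a higher response in KO was 53.7%, but 3.34% with median scaling over all probes, which moved the median of all genes to -0.27, and 71.9% over the kept probes.

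At 240 min the responses differed in 857 genes (471 higher, 386 lower in KO). Of the fixed lists, replication genes had the lowest camera adjusted p at the preset correlation. Of 24 G1/S and DNA replication genes, 12 responded less in KO and 12 did not pass (16 adjusted over the list alone), with a median log2 difference of -0.49 (camera adjusted p = 3.98e-13). Of these, Ung responded 4.04-fold less in KO by a log2 difference of -2.01±0.20 (SE, n = 3 and 4 arrays per genotype, limma adjusted p = 7.24e-08), with Cdc6 (-1.40±0.20) and Ccne2 (-1.40±0.29). Outside the list, the DNA mismatch repair gene Msh6 (-1.35±0.12), Mmp3 (-1.50±0.21, 3 of 4 WT arrays at 0 min detecting it), Plau (-1.32±0.17), Mcpt8 (-1.64±0.23) and Hes1 (-1.44±0.19) were also lower. Bmp4 passed too (-1.54±0.22), but it was not well above background in WT at 240 min, so its fall there is a lower limit and the difference in response is not measured. The response was higher in KO for the cytokine Il11 (1.92±0.18), the collagenase gene Mmp13 (1.87±0.19, 1 of 4 WT arrays at 0 min detecting it), Egr1 (1.85±0.22), Sox9 (1.78±0.16) and Inhba (1.69±0.15). For S100a8 (3.80±0.15) and Flrt3 (1.93±0.15), not well above background on any WT array, and Serpinb2 (3.19±0.14), not well above background in WT or in KO at 0 min, the fitted value is no bound. Spry3 differed too (-0.62±0.14, adjusted p = 0.00639), but with all KO arrays not well above background its response there is not measured. ERK output and feedback genes passed camera with 5 higher and 14 not called (the same adjusted over the list alone) of 19 (camera adjusted p = 0.000467), including Hbegf (1.57±0.13), a gene chosen after its values were seen. Of 17 FGF receptors, ligands and adaptors the counts were 4 higher and 13 not called (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000197). Of 19 matrix proteases and inhibitors they were 8 higher, 2 lower and 9 not called (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.86e-05). Of 19 glycolysis and hypoxia genes they were 4 higher and 15 not called (the same adjusted over the list alone, camera adjusted p = 0.0122). Extracellular matrix genes counted 4 higher and 24 not called (9 higher adjusted over the list alone) of 28 (camera adjusted p = 0.00142, adjusted p = 0.356 with an estimated correlation). The p53 target genes counted 3 lower and 14 not called (the same adjusted over the list alone) of 17 (camera adjusted p = 0.0033, adjusted p = 0.0926 with an estimated correlation). SRF/MRTF genes counted 1 higher and 16 not called (the same adjusted over the list alone) of 17 (camera adjusted p = 0.0134, adjusted p = 0.229 with an estimated correlation). ER stress genes counted 2 higher and 23 not called (the same adjusted over the list alone) of 25 (camera adjusted p = 0.0462, adjusted p = 0.0595 with an estimated correlation), their median of 0.13 turning to -0.02 with median scaling over all probes. Among genes with a higher response in KO, 281 rose in KO and 205 fell in WT. Among those with a lower response 230 fell in KO and 170 rose in WT. At any of the 4 times, 1005 genes differed by limma's F-test. The 240 min count was 534 without WT 240 min replicate B and 513 without KO 240 min replicate C. With replicates A and D at 0 min averaged, 3, 42, 126 and 535 genes differed at 15, 60, 120 and 240 min. The share higher in KO was 55%, against 33.4% with median scaling over all probes.

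**Figure D3:**
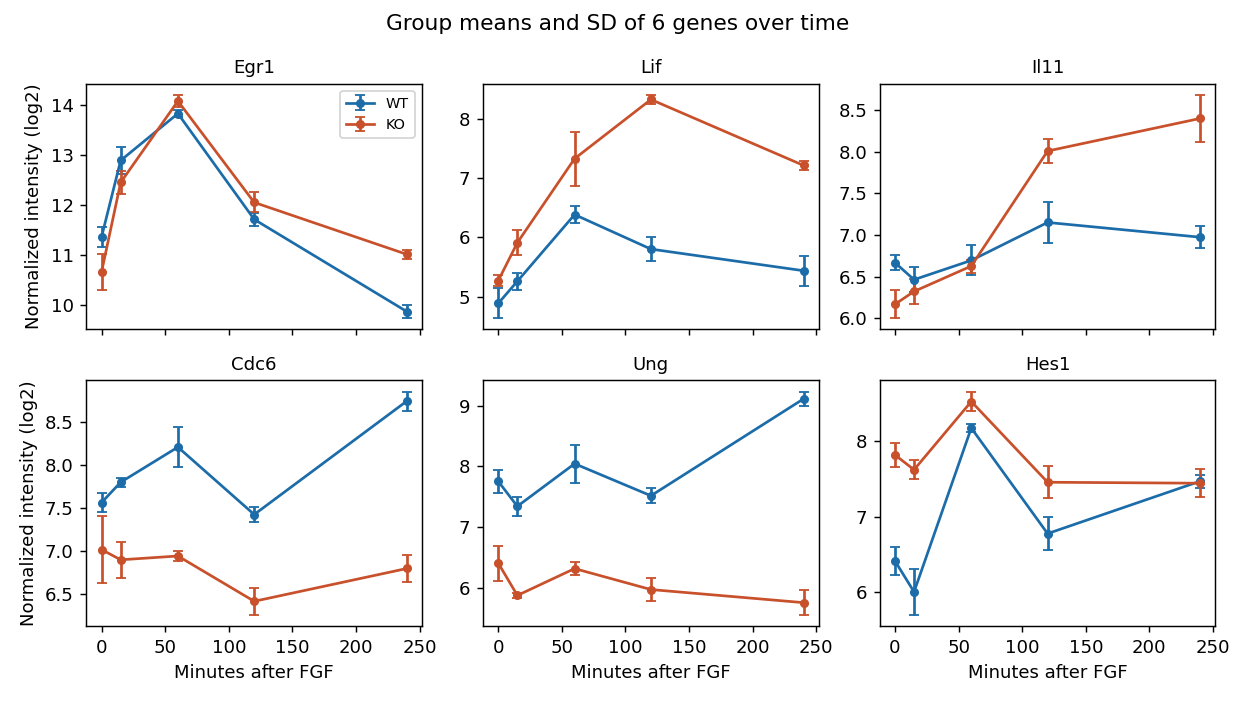
Mean normalized log2 intensity (y axes) with SD error bars of Egr1, Lif, Il11, Cdc6, Ung and Hes1 by time after FGF in minutes (x axis) in WT and KO, with 4 arrays per point at 0 min and 3 later. Relative to 0 min, Lif and Il11 rise more in KO at 120 min, and Cdc6 and Ung rise by 240 min in WT, by 1.18 and 1.36 on the log2 scale.

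**Figure D4:**
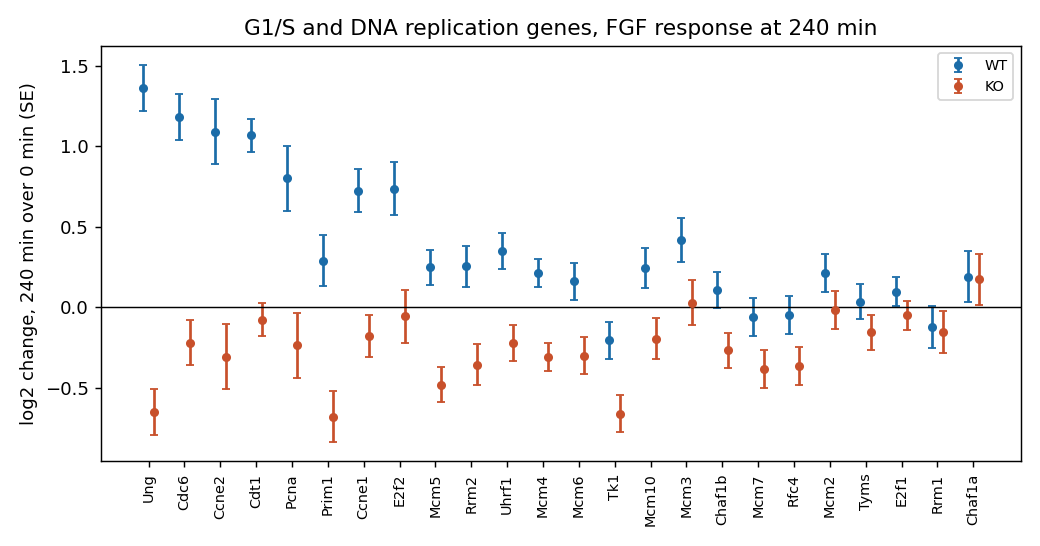
Log2 change from 0 to 240 min after FGF with standard errors (y axis) of each of the 24 G1/S and DNA replication genes tested (x axis), in WT and KO. In WT 9 of the genes rose and in KO 8 fell, and 12 differed between the genotypes.

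The Wnt pathway, named in the title of the series, was followed through 3 fixed lists holding 31 ligands, receptors and transducers, 19 antagonists and 10 beta-catenin target genes that could be tested. Before FGF, 7 were higher, 6 were lower in KO and 18 did not pass (6 were higher and 6 were lower adjusted over the list alone) in the first list. Wnt7b was 28.3-fold lower and Wnt10a at least 2.59-fold higher from not well above background. The receptors Ror2 (1.04±0.097 SE, n = 4 per genotype) and Fzd7 (0.77±0.11) were higher. Of antagonists 4 were higher, 7 were lower and 8 did not pass (the same adjusted over the list alone), with Dkk3 at least 3.69-fold lower and Apcdd1 at -0.79±0.14. Of targets 2 were higher, 2 were lower and 6 did not pass (the same adjusted over the list alone), with Msx1 at least 2-fold lower. No list passed camera (adjusted p = 0.79, 0.437 and 0.987). For ligands and receptors (median 0.01, mean -0.04) and targets (median 0.07, mean -0.06) the median and mean had opposite signs. After FGF the receptor Fzd2 fell in both genotypes, by 240 min 3.07-fold in WT (-1.62±0.15, n = 3 and 4, adjusted p = 2.53e-09) and 2.35-fold in KO (-1.23±0.15), and at 120 min 2-fold in WT (adjusted p = 3.41e-05) and 1.57-fold in KO (-0.65±0.15). At 60 min it fell in WT (-0.54±0.15), a call that ended for 4 of 7 left-out arrays (adjusted p = 0.137 without WT 60 min replicate B). Bcl9l, a beta-catenin cofactor, fell at 120 min (-0.85±0.16 in WT, -0.94±0.16 in KO) and 240 min (-1.34±0.16 and -0.97±0.16). In WT at 240 min the transcription factors Tcf7l2 (-1.24±0.13) and Tcf7l1 (-0.95±0.091) and the target Ccn4 (-0.94±0.081) fell and cyclin D1 gene Ccnd1 (0.70±0.10) rose. In WT the agonist Rspo2 (1.06±0.22) rose and the corepressor Tle1 (-0.63±0.12) fell at 60 min. Wnt7a rose in WT at 120 min (0.61±0.16, detected on 1 of 4 arrays at 0 min), a call lost for 4 of 7 left-out arrays (adjusted p = 0.135 without WT 120 min replicate A). In KO at 240 min Wnt7a (0.72±0.16) rose and Tle4 (-0.63±0.090), Ccn4 (-0.59±0.081) and Apcdd1 (-0.60±0.15) fell, the call of Apcdd1 ending without KO 240 min replicate C (0.0537).

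By count, the ligands, receptors and transducers had 2 up and 3 down in WT at 60 min, 2 up and 3 down at 120 min and 3 up and 8 down at 240 min. In KO they had 0 up and 1 down, 0 up and 5 down and 5 up and 8 down. At 15 min 1 member passed in WT and 1 in KO. Antagonists had 0 up and 1 down, 0 up and 1 down and 0 up and 3 down in WT at 60, 120 and 240 min, and 1 up and 1 down, 0 up and 2 down and 2 up and 2 down in KO. Targets had 1 up and 0 down at 60 min and 3 up and 1 down at 240 min in WT, and 1 up and 0 down and 1 up and 1 down in KO. At 120 min 0 targets were called by limma in either genotype, with 0 in WT and 2 in KO at an unadjusted p under 0.05. None of the 3 Wnt lists passed camera in any FGF response, the lowest adjusted p being 0.0882 for the first list in WT at 240 min. The test of the difference between genotypes at 240 min counted 4 higher in KO and 27 not called (the same adjusted over the list alone) for ligands, receptors and transducers (camera adjusted p = 0.129). For antagonists it counted 1 higher, 1 lower and 17 not called (3 higher and 2 lower adjusted over the list alone), and for targets 2 lower and 8 not called (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.541 for both). Wnt genes with a higher response in KO, chosen after their values were seen, were Tcf7l2 (0.80±0.18, adjusted p = 0.00476) and Tcf7l1 (0.43±0.13, 0.0359). Both fell more than this in WT. Also higher were the receptor Ryk (0.40±0.10, 0.014) and the antagonist Tpbg (0.41±0.11, 0.0238). Ccnd1 (-0.72±0.14, 0.0018), Msx2 (-0.67±0.20, 0.0435, with 3 of 4 WT arrays at 0 min detecting it) and Apcdd1 (-0.69±0.21, 0.0442) were lower. Wnt16 passed as well (adjusted p = 0.0314) but was not well above background at 240 min in either genotype and was detected on 1 of 4 WT and 0 of 4 KO arrays at 0 min, so no fold is given. At 60 min the response of Fzd2, chosen in the same way, was higher in KO (0.86±0.21, adjusted p = 0.0455). At 120 min 0 Wnt genes of the 3 lists differed by limma, with 5, 5 and 2 at an unadjusted p under 0.05. At 15 min 0 did too (2, 0 and 1 at that limit). Leaving out 1 array ended the call of Fzd2 at 60 min for 10 of 14 arrays (adjusted p = 0.203 without KO 60 min replicate C) and of Apcdd1 for 11 (0.16 without KO 240 min replicate C). It ended those of Tcf7l1 and Msx2 for 9 each (0.107 without WT 240 min replicate C and 0.123 without replicate A). It also ended those of Wnt16 for 6, Tpbg for 4 and Ryk for 1 (0.0986, 0.0931 and 0.0505 without KO 240 min replicate C). Those of Tcf7l2 and Ccnd1 held without any array.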

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

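The tests of other differences between the lines and of fewer cells in cycle were chosen only after the results were seen. The responses of the genotypes differed by the interaction test in 6, 77, 203 and 857 genes at 15, 60, 120 and 240 min and in 1005 at any time. The log2 differences (KO minus WT response) that passed among the genes named for this test and the Sprouty genes were, at 15 min, Sema7a 1.35, Hbegf 0.88, Errfi1 0.71, Id1 0.68 and Klf2 0.60. At 60 min they were Xist 1.62, Zfp36 1.46, Klf2 1.005, Egr1 0.96, Cxcl1 -1.65, Chac1 -1.51, Hes1 -1.06, Tnfaip3 -0.97, Gadd45g -0.92 and Fzd2 0.86. At 120 min they were Csf2 2.80, Lif 2.14, Il6 2.10, S100a8 1.83, Socs3 1.41, Csrnp1 1.40, Il11 1.35, Edn1 -1.26, Pcna -1.20 and Rnd3 -0.88. At 240 min they were S100a8 3.80, Serpinb2 3.19, Il11 1.92, Mmp13 1.87, Egr1 1.85, Sox9 1.78, Inhba 1.69, Ung -2.01, Mcpt8 -1.64, Bmp4 -1.54, Mmp3 -1.50, Hes1 -1.44, Cdc6 -1.40, Ccne2 -1.40, Msh6 -1.35, Plau -1.32, Tcf7l2 0.80, Tcf7l1 0.43, Ryk 0.40, Wnt16 0.57, Apcdd1 -0.69, Tpbg 0.41, Ccnd1 -0.72, Msx2 -0.67, Flrt3 1.93, Hbegf 1.57 and Spry3 -0.62. The value of Wnt16, not well above background at 240 min in either genotype, is fitted and gives no fold. Those of Csf2, S100a8, Serpinb2, Flrt3, Spry3 and Bmp4 are fitted too, since each gene was not well above background in at least 1 of the 4 groups compared. For Bmp4 that group is WT at 240 min, so its fall in WT is a lower limit and a lower response in KO is not shown. Sema7a, Lif, Il6, Edn1, Mmp13, Mmp3 and Msx2 were above background on only part of the arrays of a group.

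Among 320 groups of 4 arrays at 0 min (named genes and array measures), 22 (6.88%) held 1 array far from the others, where chance marks about 1 in 20. The ratio of its gap to the whole range was, for WT replicate C, Atf3 0.831, Bcl9l 0.872, Ccn4 0.838, Ddit3 0.941, Igfbp5 0.863, Tcf7l1 0.888, Thbs1 0.868 and Tk1 0.848, and for WT replicate B Gadd45g 0.88, Hk2 0.898, Svop 0.863 and the median bead count per probe 1. For WT replicate D it was Lcn2 0.851 and the 5th percentile of intensity 0.92, for KO replicate A Ccn4 0.861, for KO replicate D Fas 0.842, Mest 0.873 and Ndn 0.96, and for KO replicate C Gap43 0.867, Rgcc 0.841, Rrm2 0.91 and Tle1 0.835. WT replicate C held 8 of the 22.

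Spry3, which the labels do not list as deleted, was not detected on any KO array. A lost chromosome segment around Spry3 would lower its neighbours too, and Vamp7, the only neighbour that could be tested, lay at a log2 of -0.47 (SE 0.088) in KO at 0 min, too close to the bound of -0.5 set beforehand to decide. Loss of the segment and an effect of the Sprouty deletion or of the line on Spry3 expression therefore cannot be told apart here, since 1 neighbour decides little.

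Nearly as many genes differed between KO and WT at 0 min as did not, and KO arrays had a narrower background. A different background as the cause would place the calls among dim genes, but 61.1% of the 2726 brightest genes were called against 20.2% of the 2726 dimmest, which argues against it. Other differences between the lines than the deletion remain open, and the Hox and limb position genes, which mark where in the embryo cells came from, do not decide it. Of these, 12 of 27 were called, where 45.8% of all genes were. With 1 kind of WT and 1 kind of KO cells, line and genotype cannot be told apart, and an effect of the deletion stays untested. With no slide given, array processing cannot be told apart from genotype either.

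G1/S genes responded less in KO at 240 min, with a median difference of -0.49. This did not rest on 1 array, as the median stayed at or below -0.456 in every fit without 1 array (lowest -0.61). A lower starting level in KO could not be decided. Across the 24 genes the 0 min level and the difference gave a Spearman rho of -0.188 (bootstrap SD 0.212). A shift they all share would not show. Fewer cells in cycle could not be decided: G2/M genes had a median of -0.046 (SD over members 0.28), and they may respond later than 240 min. An effect of the Sprouty deletion on entry into S phase is thus a hypothesis that was not tested. It stays open beside a lower starting level and differences between the lines.

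Other splits of the arrays, taken as independent, cannot exclude chance differences between cultures. For KO against WT at 0 min, 1 of 35 splits, the real one, gave 4995 genes or more (highest other 588). The same held with 1 of 35 splits for the WT responses at 15, 60, 120 and 240 min (250, 572, 438 and 1743 genes against at most 44, 297, 187 and 1185) and the KO responses (89, 617, 1654 and 2322 against 15, 355, 712 and 1272). It also held for the averaged difference (1 of 100 drawn splits, 7351 against 3450), and for the differences of response at 60 and 120 min and at any time (1 of 100 each, 77, 203 and 1005 against 6, 9 and 387). At 15 and 240 min 2 of 100 splits, the real one among them, gave as many genes or more, a share under the limit of 0.05, though 1 other split gave more, with 6 and 857 genes against at most 13 and 1141. For KO against WT at 15, 60, 120 and 240 min there are 10 splits, too few to give a share under 0.05, with 4353, 4579, 4775 and 4782 genes in the real split and 0 as the highest other.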

How the results depend on the processing

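Averaging replicates A and D at 0 min and median scaling over the kept probes were tests chosen only after the data were seen. Of 263 comparisons of a named gene, 232 kept their direction and their side of the threshold under every alternative, leaving out 1 array included. The other 31 did not. Over 2254 fits without 1 array, 2144 did and 110 lost the call. Among the other alternatives, a fit of the compared groups alone lost 20 calls and the replicate block within each genotype 18 of 207. Averaging A and D at 0 min lost 14, median scaling over all probes 11 and the replicate block 9. Counts of called genes for KO against WT at every time and averaged stayed within 1.5 times of the main count under every alternative, as did the KO count at 240 min. No slide block was run. Signal over background limits the 2726 dimmest genes (20.2% called at 0 min) and leaves Spry1 and Spry2 unread.

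With median scaling over all probes the calls were 133 at 15 min and 290 at 120 min in WT, 36 at 15 min and 3889 at 120 min in KO, and 213, 2516 and 2063 for the difference at 60 min, 120 min and any time. This scaling takes the array median, which lies near background, as its anchor. Over the kept probes the KO count at 120 min was 2547 and the difference at 120 min 516. The difference at 15 min was 13 without normexp and 11 with the stricter filter, which tests fewer genes. Array weights gave 212 in KO at 15 min, 13 for the difference at 15 min and 1525 at any time. With A and D at 0 min averaged, which leaves fewer samples, the counts were 43 and 322 in KO at 15 and 60 min, and 3, 42, 126 and 535 for the differences at 15, 60, 120 and 240 min. A fit of the compared groups alone, with fewer samples to estimate the spread, gave 25, 273, 178 and 994 in WT at 15, 60, 120 and 240 min, 10 and 219 in KO at 15 and 60 min, and 34, 102 and 534 for the differences at 60, 120 and 240 min. Xist between KO and WT at 0 min, which did not pass (-0.17), turned to 0.0052 with median scaling over all probes and to 0.093 with the mean of its probes. Except where the construction is named, the cause was not tested.

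The replicate letters pair no samples: the mean correlation of deviations was -0.0118 for arrays of the same letter and 0.00492 for others, and 1 of 45 pairs of groups exceeded 0.1. With the letter as a replicate block the counts were 46 and 386 in KO at 15 and 60 min and 3 for the difference at 15 min. With the block set within each genotype they were 161 in WT at 15 min, 30 and 278 in KO at 15 and 60 min, and 3, 26, 133, 485 and 663 for the differences at 15, 60, 120 and 240 min and at any time.

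Lists passing camera fell with an estimated correlation from 5 to 3 for KO against WT at 0 min, from 58 to 33 over the FGF responses and from 24 to 9 over the differences. The test fry, which does not compare a list with other genes, called 23 at 0 min. Across all genes in place of those called, the correlation of the WT and KO responses was 0.313, 0.450, 0.423 and 0.452 at 15, 60, 120 and 240 min. With median scaling over the kept probes it was 0.505 at 120 min.

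Leaving out 1 array at a time gave 4615 to 4770 genes for KO against WT at 0 min, 3843 to 3935, 4015 to 4219, 4230 to 4428, 4260 to 4491 at 15, 60, 120 and 240 min, and 7237 to 7350 averaged. In the same order of times the WT responses ranged over 101 to 201, 375 to 541, 291 to 416, 1274 to 1789, the KO responses over 20 to 72, 258 to 733, 1160 to 1514, 1558 to 2218 and the differences over 3 to 9, 52 to 103, 125 to 233, 513 to 1076, with 764 to 1182 at any time. The fitted log2 difference between KO and WT of Spry4 ranged over -0.80 to -0.60 at 0 min and -1.03 to -0.85 at 120 min. The other fitted ranges measure no fold, because the probe was not above background. In KO alone that was so for Spry4 at 60 and 240 min (-1.34 to -1.12 and -1.41 to -1.08) and for Spry3 at 0 to 240 min (-2.06 to -1.92, -2.68 to -2.49, -2.25 to -2.17, -2.51 to -2.39, -2.68 to -2.51). At 15 min it was so for Spry4 in both genotypes (-0.27 to -0.08), so nothing was measured there. In KO at 0 min Spry4 was above background on 1 of 4 arrays.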

Other observations

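The zinc finger test was chosen only after the result was seen. Genes were also grouped by the time of their largest change, more often 120 min in KO than in WT. Of 2310 genes called at any time in WT, 702 rose and 798 fell most at 240 min, and 103 and 109 at 120 min. Of 3505 in KO, 901 and 980 did so at 240 min and 417 and 717 at 120 min. At 60 min it was 252 and 180 in WT and 237 and 184 in KO. At 15 min it was 94 and 72 against 25 and 44. That difference was not tested, and KO arrays at 120 min detected fewer probes.

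Zfp41 in WT and Zkscan14 and Zfp87 in KO fell at 60 min, and a fall shared by this family of zinc finger genes was taken as a hypothesis. Over the other 189 tested Zfp and Zkscan genes, leaving out the 13 named by the rule, the median log2 change at 60 min was -0.08 in WT and -0.08 in KO. Of these 189 genes 8 rose and 19 fell in WT and 3 rose and 15 fell in KO, so most were not called. Both medians lay below those of all 10000 random lists of the same size matched on mean level (percentile 0). At 120 min the KO median did so too (-0.12, percentile 0), but the WT median did not stand apart (-0.03, percentile 6.18). Nor did the medians at 15 min (percentile 55.6 in WT and 97.0 in KO) or 240 min (22.7 in WT and 18.1 in KO). The family may therefore fall slightly at 60 min in both genotypes, and whether the genotypes differ at 120 min was not tested. Random lists ignore the correlation between related genes and probes, so the percentile overstates how far the family stands apart.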
